A study of Mus musculus with 10 samples.

How the data were processed

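RNA from CD4-positive spleen cells, taken with magnetic beads from female NOD and B10 mice of 8 weeks, was measured on 10 Affymetrix mouse gene arrays, 1 array per sample. The labels name the genotypes NODk and B10Br. Arrays fall into 4 groups by strain and state. Each strain has 3 unstimulated (T0) arrays and 2 stimulated (T1) arrays. Stimulated cells received PMA at 10 ng/ml with ionomycin at 1 uM for 4 hours. The labels call T0 basal, but the protocol can be read as culture of unstimulated cells for 4 hours, so T0 handling is unclear. The samples are labelled biological replicates, without saying which animal each came from.

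The deposited values are log2 intensities, made by the authors with RMA in Affymetrix Power Tools (RMA corrects background, brings all arrays to one distribution of values and summarises probes). No version or option was given, and the log base was inferred from the range of the values. Array medians lay between 6.18 and 6.23. Detection calls and background levels are not used here. A fold change of a gene near background is therefore understated by an unknown amount. The small number of arrays limits precision. Pearson's r between arrays, over all probe sets, was 0.985 to 0.993 within groups and 0.943 to 0.984 between groups.

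The table holds 35486 probe sets. The platform table gives 1 gene symbol for 21789 of them, several for 1621 and no listed gene for 12076. The probe set with the highest mean over all arrays stood for each of 19938 genes, of which 999 had more than 1 probe set. Probe sets with several or no symbols were left out of the gene tests and entered only in an alternative. For 91 of the probe sets with 1 symbol, the gene identifier was not in the mouse RefSeq annotation (assembly GRCm38.p6), used only for names and gene order. The table names no assembly for its probes, so no positions are given.

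Differences were tested with limma 3.58.1 in R 4.3.3. A model of 4 group means was fitted to all 10 arrays at once (6 residual degrees of freedom, prior degrees of freedom 6.30), with eBayes and two-sided tests. The 5 contrasts were stimulation in each strain, NOD minus B10 at T0 and at T1, and the interaction of strain and stimulation (NOD response minus B10 response). P-values were adjusted by Benjamini-Hochberg over all genes in each contrast, with a threshold of 0.05. Values are log2 differences of group means (n = 3 arrays at T0, n = 2 at T1), with limma's standard error where shown.

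The contrasts, the tests, 19 gene lists, 10 cell type marker lists, the rule for named genes and most alternatives were fixed before the data were examined. Lists were tested with camera at a preset correlation of 0.01 between genes, and p-values were adjusted within each kind of list and contrast. The list test was repeated with an estimated correlation. Named genes were the 15 largest rises and 10 largest falls in each stimulation contrast, and the 10 largest positive and 10 largest negative values in each of the others. They had to pass the threshold and, outside the interaction, to show no overlap between the single arrays of both groups. Predicted or unnamed genes, olfactory and vomeronasal receptors, small RNA genes and immunoglobulin or T cell receptor segments were left out of this choice. Members of the fixed lists may be named too.

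The procedure was tested on simulated data of the same design but with fewer changed genes than most contrasts called, so rates may differ here. Of genes given a 2-fold change, it called 86.6% in each stimulation contrast, 94.0% between strains at T0, 88.1% at T1 and 61.2% in the interaction. At 1.41-fold these shares were 28.4% in B10, 35.8% in NOD, 55.2%, 19.4% and 7.46%. Of the calls in these contrasts, 14 of 157, 8 of 156, 10 of 175, 5 of 142 and 6 of 116 were false. Camera recovered 50 of 50 lists of 20 uncorrelated genes shifted by 0.3 (log2), and called 1 of 50 not shifted. Smaller shifts, as in many lists between strains, were not simulated.

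Alternatives were each array shifted to one 75th percentile, the mean of all probe sets of a gene, every probe set of the table, only the brighter genes, eBayes with trend and robust settings, array weights, only the arrays of the groups compared, a minimum change of 2-fold, replicate number as a fixed or random block, and omission of each array in turn. Lists were also tested with fry. Replicate numbers repeat across states. Correlations of the arrays' deviations from their group means did not all reach the minimum of 0.1 set for pairing, so no block was used in the main fit. Between T0 and T1 they were 0.41 and 0.40 for replicates 2 and 3 of B10, and -0.014 and 0.22 for those of NOD. A shared source of arrays with one number thus stays possible, above all in B10. After the data were seen, 2 alternatives were added. One used the mean of the erythroid markers Alas2, Klf1 and Car2 on each array as a covariate, and the other left out both B10 arrays of replicate 3. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.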

Results

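CD4-positive spleen cells of NOD mice were compared with those of B10 mice before and after stimulation with PMA and ionomycin. This pair of drugs triggers the protein kinase C and calcium branches of T cell receptor signalling. Each strain had 3 unstimulated (T0) and 2 stimulated (T1) arrays, and 19938 genes were tested. T1 replicate 1 is not analysed here in either strain. The comparisons ask which genes responded in each strain, which differed between strains in each state, and which responses differed between strains.

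Cytokine genes led the rises on stimulation in both strains. Il2, the T cell growth factor, rose 68.7-fold in B10 (log2 change 6.10 ± 0.13, adjusted p = 4.42e-11) and 35.8-fold in NOD (5.16 ± 0.13, adjusted p = 1.44e-10). Il3, which acts on blood cell precursors, rose 76.0-fold in B10 (6.25 ± 0.17) and 34.6-fold in NOD (5.11 ± 0.17). For neither gene did the interaction of strain and stimulation pass the threshold. Il2 was already higher in NOD at T0 (6.50 against 5.95 in B10), and this difference passed. Ifng, the macrophage-activating cytokine, rose by 4.22 in B10 and 4.21 in NOD on the log2 scale. S1pr1, the receptor that guides T cells out of lymphoid organs, fell 17.0-fold in B10 (-4.09 ± 0.15) and 19.5-fold in NOD (-4.29 ± 0.15). The call count was 6342 genes in B10 (2729 rose, 3613 fell) and 7085 in NOD (3201 rose, 3884 fell). At least a 2-fold change was seen for 1876 of these genes in B10 and 1812 in NOD.

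Both strains shared most of the response. In both, 2043 genes rose, against 438 if calls were independent, and 3139 fell, against 704. Both strains used the same spread estimate per gene, so calls were not fully independent. Opposite calls were made for 12 genes. Across genes, Pearson's r between both responses was 0.912 and the Spearman rank correlation 0.770, with genes not being independent replicates. With every array shifted to one 75th percentile, the median change of all genes in NOD moved from 0.081 to 0.21, and the count became 8538, with 5393 higher and 3145 lower. The balance of rises and falls in NOD is therefore relative to the scaling.

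**Figure D1:**
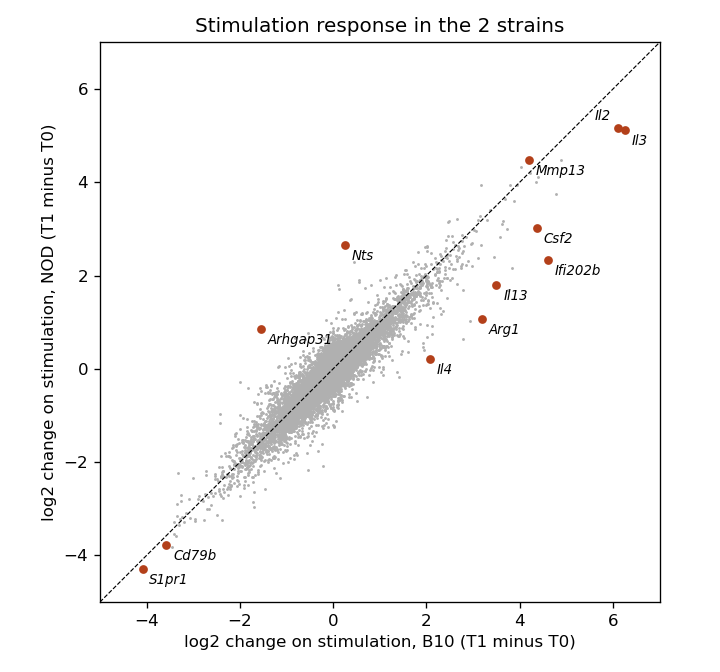
Each point is 1 gene, with its log2 change on stimulation (T1 minus T0) in B10 on the x axis and in NOD on the y axis, and the dashed line marks equal change. Il2 and Il3 lie at the upper end in both strains, S1pr1 at the lower end, and Il4 (2.08 in B10, 0.20 in NOD) lies far below the line.

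The cytokine list rose as a group. Of 18 measured effector cytokine genes, 16 rose and 0 fell in B10 (16 and 0 adjusted over the list alone, median 3.77, camera adjusted p = 1.8e-15, adjusted p = 0.0513 with an estimated correlation). In NOD, 14 rose and 0 fell (14 and 0 adjusted over the list alone, median 2.22, camera adjusted p = 1.54e-11, adjusted p = 0.102 with an estimated correlation). Il17f and Il17a, cytokines that recruit neutrophils, rose by 4.88 and 4.78 in B10 and by 4.48 and 3.75 in NOD. Il10, an anti-inflammatory cytokine, rose by 4.39 in B10 and 4.11 in NOD. Csf2, which encodes GM-CSF, rose by 4.37 and 3.03, and Lif by 3.80 and 3.95. In B10, Il4, Il5 and Il13, the type 2 cytokines, rose by 2.08, 3.74 and 3.50. In NOD, Il5 and Il13 rose by 1.69 and 1.80, while Il4 had a value of 0.20 (adjusted p = 0.481).

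Of 16 measured chemokine and receptor genes, 9 rose and 2 fell in B10 (11 and 3 adjusted over the list alone, median 1.14, camera adjusted p = 4.58e-05, adjusted p = 0.207 with an estimated correlation). In NOD, 9 rose and 4 fell (10 and 4 adjusted over the list alone, median 1.56, camera adjusted p = 0.0032, adjusted p = 0.423 with an estimated correlation). Ccl3 and Ccl4, which attract macrophages and T cells, rose by 3.88 and 4.04 in B10 and by 3.60 and 4.32 in NOD. Xcl1, which attracts cross-presenting dendritic cells, rose by 2.62 and 2.13. Of 17 activation surface molecules, 12 rose and 0 fell in B10 (12 and 0 adjusted over the list alone, median 1.06, camera adjusted p = 5.82e-08, adjusted p = 0.178 with an estimated correlation). In NOD, 12 rose and 1 fell (13 and 1 adjusted over the list alone, median 0.96, camera adjusted p = 1.98e-06, adjusted p = 0.222 with an estimated correlation). Il2ra, a chain of the IL-2 receptor, rose by 3.14 in B10 and 3.29 in NOD. Slamf1, a costimulatory receptor, rose by 3.16 and 3.94, with an interaction of 0.77 (adjusted p = 0.0429). This interaction call ended on omission of each of the 10 arrays (values over omissions 0.72 to 0.83), and with every array shifted to one 75th percentile, every probe set tested, array weights, a replicate block or without both B10 arrays of replicate 3. Icos, another costimulatory receptor, fell in NOD (-0.68) and had a value of 0.11 in B10 (adjusted p = 0.638), with an interaction of -0.79 that did not pass (adjusted p = 0.173).

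Transcription factors of the immediate response rose. Of 24 measured AP-1, EGR, NR4A and NF-kB genes, 17 rose and 1 fell in B10 (17 and 1 adjusted over the list alone, median 1.25, camera adjusted p = 7.79e-10, adjusted p = 0.165 with an estimated correlation). In NOD, 18 rose and 1 fell (19 and 1 adjusted over the list alone, median 0.97, camera adjusted p = 3.52e-09, adjusted p = 0.19 with an estimated correlation). Myc, a driver of cell growth, rose by 3.17 in B10 and 2.67 in NOD, Egr2 by 2.02 and 1.97, and Nr4a1 by 1.42 and 1.42. Ikzf1, a lymphoid transcription factor, was the member that fell in both strains (-0.35, -0.38). Without B10_T0 replicate 1 or 3 or B10_T1 replicate 2 its call in B10 ended (range over omissions -0.52 to -0.18), as it did in NOD without NOD_T0 replicate 1 or 2 or NOD_T1 replicate 3 (-0.46 to -0.31). Its calls also ended in both strains with every array shifted to one 75th percentile, in B10 with every probe set tested or only the arrays of these groups, and in NOD with array weights. Of 25 negative feedback regulators, 19 rose and 2 fell in B10 (21 and 2 adjusted over the list alone, median 1.08, camera adjusted p = 1.75e-09, adjusted p = 0.178 with an estimated correlation). In NOD, 20 rose and 2 fell (20 and 2 adjusted over the list alone, median 1.03, camera adjusted p = 1.17e-08, adjusted p = 0.205 with an estimated correlation). Spry1, an inhibitor of growth factor signalling, rose by 4.34 and 4.00. Outside the lists, Mmp13, a collagenase, rose by 4.20 and 4.48, and Mfsd2a, a lipid transporter, by 3.94 and 3.94. Prrg4, a membrane protein, rose by 3.37 in B10 and 3.41 in NOD.

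Genes of the resting state fell. Of 18 measured naive and resting T cell genes, 12 fell and 0 rose in B10 (14 and 0 adjusted over the list alone, median -0.75, camera adjusted p = 3.89e-08, adjusted p = 0.178 with an estimated correlation). In NOD, 15 fell and 0 rose (15 and 0 adjusted over the list alone, median -0.65, camera adjusted p = 3.54e-08, adjusted p = 0.205 with an estimated correlation), and 10 fell with every array shifted to one 75th percentile. Besides S1pr1, the transcription factor Lef1 fell (-1.70 in B10 and -1.71 in NOD). The gut homing receptor Ccr9 fell (-2.37 and -3.25), as did the lymph node homing receptor Ccr7 (-0.56 and -0.71). Ccng2, which encodes a cyclin of resting cells, fell in both strains (-3.42 in B10, -3.28 in NOD). Cd55, which protects cells from complement, also fell (-3.31, -3.35), as did Tdrp, Tmem71 and Cep97 (all between -3.82 and -3.36). Falls in both strains, given for B10 and then NOD, were also seen for Fbxo32 (-3.36, -3.16), a ubiquitin ligase subunit, Fam78a (-3.35, -2.89) and Tcp11l2 (-3.32, -2.23). Slc40a1 (-3.19, -3.29), the iron exporter ferroportin, and Rflnb (-2.95, -3.26) fell too. Monocyte and macrophage markers fell in these arrays too (medians -1.53 and -1.82).

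Growth and biosynthesis lists moved up in both strains. Of 20 ribosome biogenesis genes, 19 rose and 0 fell in B10 (20 and 0 adjusted over the list alone, median 1.61, camera adjusted p = 6.28e-18, adjusted p = 0.0513 with an estimated correlation). In NOD, 20 rose and 0 fell (20 and 0 adjusted over the list alone, median 1.47, camera adjusted p = 5.6e-16, adjusted p = 0.098 with an estimated correlation). Polr1b, a subunit of RNA polymerase I, rose by 2.28 and 2.46. The amino acid starvation list (13 measured) had 9 that rose and 0 that fell in B10 (10 and 0 adjusted over the list alone, median 0.64, camera adjusted p = 7.66e-06, adjusted p = 0.188 with an estimated correlation). In NOD, 9 rose and 0 fell (9 and 0 adjusted over the list alone, median 0.91, camera adjusted p = 5.18e-06, adjusted p = 0.205 with an estimated correlation). Asns, asparagine synthetase, rose by 2.86 and 2.23. For cholesterol synthesis (14 measured), 9 rose and 2 fell in B10 (9 and 2 adjusted over the list alone, median 0.77, camera adjusted p = 0.000695, adjusted p = 0.178 with an estimated correlation). In NOD, 8 rose and 0 fell (9 and 0 adjusted over the list alone, median 0.58, camera adjusted p = 0.00199, adjusted p = 0.205 with an estimated correlation). Sqle, squalene epoxidase, rose by 2.12 and 1.84. For glycolysis and nutrient transport (17 measured), 7 rose and 2 fell in B10 (9 and 2 adjusted over the list alone, median 0.26, camera adjusted p = 0.00578, adjusted p = 0.438 with an estimated correlation). In NOD, 9 rose and 2 fell (9 and 3 adjusted over the list alone, median 0.37, camera adjusted p = 0.0179, adjusted p = 0.596 with an estimated correlation). Hk2, a hexokinase, rose by 2.35 and 2.32. The lactate exporter Slc16a3 fell in both strains (-1.16 in B10 and -0.78 in NOD), a call that ended in NOD without NOD_T1 replicate 2 (values over omissions -1.08 to -0.49).

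Other lists moved less uniformly. Of 14 MHC and antigen presentation genes, 7 fell and 0 rose in B10 (9 and 0 adjusted over the list alone, median -0.44, camera adjusted p = 0.00134, adjusted p = 0.413 with an estimated correlation). In NOD, 2 rose and 9 fell (2 and 9 adjusted over the list alone, median -0.63, camera adjusted p = 0.000992, adjusted p = 0.423 with an estimated correlation). H2-Ea, an MHC class II chain that B cells and myeloid cells express, had values of -0.83 in B10 and -1.85 in NOD. B cell markers (medians -0.88 and -0.91) and monocyte and macrophage markers (medians -1.53 and -1.82) fell as well. Of 20 interferon-stimulated genes, 9 fell and 0 rose in B10 (10 and 0 adjusted over the list alone, median -0.53, camera adjusted p = 0.00186, adjusted p = 0.438 with an estimated correlation). In NOD, 3 rose and 4 fell (6 and 4 adjusted over the list alone, median 0.22, camera adjusted p = 0.725). With every array shifted to one 75th percentile, 8 of these genes rose and 3 fell in NOD, so the balance of this list depends on the scaling. Of 9 heat shock genes, 6 rose and 1 fell in B10 (7 and 1 adjusted over the list alone, median 0.60, camera adjusted p = 0.00139, adjusted p = 0.226 with an estimated correlation). In NOD, 4 rose and 1 fell (4 and 1 adjusted over the list alone, median 0.28, camera adjusted p = 0.23), and the list passed with fry (adjusted p = 0.00847). For cell cycle (19 measured), 4 fell and 0 rose in B10 (4 and 0 adjusted over the list alone, median -0.084, camera adjusted p = 0.174). In NOD, 4 fell and 0 rose (4 and 0 adjusted over the list alone, median -0.12, camera adjusted p = 0.137). The cell cycle list passed in B10 with a replicate block (adjusted p = 0.0348) and with the erythroid covariate (0.0456).

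Several lists held members moving both ways and did not pass the list test with camera at the preset correlation in either strain. Among 15 apoptosis regulators, 5 rose and 4 fell in B10 (5 and 5 adjusted over the list alone, median -0.031, camera adjusted p = 0.516, mean 0.25). In NOD, 5 rose and 5 fell (5 and 5 adjusted over the list alone, median 0.028, camera adjusted p = 0.725). Bcl2l1, which encodes the survival factor Bcl-xL, rose by 2.23 and 2.08, and Bcl2, another survival factor, fell (-0.78 and -0.91). Among 16 T helper lineage regulators, 5 rose and 6 fell in B10 (5 and 8 adjusted over the list alone, median -0.26, camera adjusted p = 0.845, mean 0.098). In NOD, 6 rose and 6 fell (6 and 7 adjusted over the list alone, median -0.17, camera adjusted p = 0.913, mean 0.073). Tbx21, the regulator of the type 1 lineage, rose by 2.47 and 3.15. For regulatory T cell genes (13 measured), 2 rose and 5 fell in B10 (4 and 6 adjusted over the list alone, median -0.27, camera adjusted p = 0.249). In NOD, 2 rose and 2 fell (2 and 2 adjusted over the list alone, median -0.15, camera adjusted p = 0.725). For T cell receptor signalling (19 measured), 4 rose and 10 fell in B10 (4 and 10 adjusted over the list alone, median -0.30, camera adjusted p = 0.139). In NOD, 6 rose and 8 fell (6 and 9 adjusted over the list alone, median -0.15, camera adjusted p = 0.255). For diabetes candidate genes of NOD mice (19 measured), 6 rose and 5 fell in B10 (8 and 7 adjusted over the list alone, median 0.20, camera adjusted p = 0.447). In NOD, 7 rose and 6 fell (9 and 6 adjusted over the list alone, median 0.11, camera adjusted p = 0.629). With the scaling to one 75th percentile, 9 diabetes candidates rose and 3 fell in NOD, and 4 regulatory T cell genes rose and 2 fell. With replicate number as a random block the diabetes candidates passed the list test (adjusted p = 0.0217 in B10 and 0.0166 in NOD). With fry, which does not compare a list with other genes, they passed too (0.0021 and 0.00131), as did apoptosis regulators (0.00339 and 0.00366) and, in B10, T cell receptor signalling (0.0327).

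Markers of the sorted cells and of other cell types fell with stimulation too. Of 7 CD4 T cell markers, 4 fell and 0 rose in B10 (4 and 0 adjusted over the list alone, median -0.98, camera adjusted p = 0.00949, adjusted p = 0.255 with an estimated correlation). In NOD, 1 rose and 4 fell (1 and 4 adjusted over the list alone, median -0.95, camera adjusted p = 0.00508, adjusted p = 0.224 with an estimated correlation). Cd4 itself had values of -1.46 in B10 and -1.72 in NOD. Of 10 monocyte and macrophage markers, 10 fell and 0 rose in B10 (10 and 0 adjusted over the list alone, median -1.53, camera adjusted p = 5.34e-07, adjusted p = 0.255 with an estimated correlation). In NOD, 10 fell and 0 rose (10 and 0 adjusted over the list alone, median -1.82, camera adjusted p = 2.31e-08, adjusted p = 0.162 with an estimated correlation). B cell markers (9 measured) gave 1 that rose and 5 that fell in B10 (1 and 6 adjusted over the list alone, median -0.88, camera adjusted p = 0.00949, adjusted p = 0.289 with an estimated correlation). In NOD, 7 fell and 0 rose (7 and 0 adjusted over the list alone, median -0.91, camera adjusted p = 1.18e-05, adjusted p = 0.162 with an estimated correlation). Cd79b, an antigen receptor chain, fell (-3.57 and -3.78). Neutrophil markers (8 measured) gave 0 that rose and 4 that fell in B10 (0 and 4 adjusted over the list alone, median -0.71, camera adjusted p = 0.00949, adjusted p = 0.255 with an estimated correlation). In NOD, 6 fell and 0 rose (6 and 0 adjusted over the list alone, median -1.24, camera adjusted p = 0.000301, adjusted p = 0.162 with an estimated correlation).

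The remaining marker lists moved in few members. For dendritic cells (7 measured), 3 fell and 0 rose in B10 (5 and 1 adjusted over the list alone, median -0.31, camera adjusted p = 0.0291, adjusted p = 0.255 with an estimated correlation). In NOD, 1 rose and 4 fell (2 and 4 adjusted over the list alone, median -0.66, camera adjusted p = 0.0566). For NK cells (7 measured), 2 fell and 0 rose in B10 (2 and 0 adjusted over the list alone, median -0.087, camera adjusted p = 0.0678). In NOD, 2 fell and 0 rose (2 and 0 adjusted over the list alone, median -0.13, camera adjusted p = 0.178). For CD8 T cells (2 measured), 2 fell and 0 rose in B10 (2 and 0 adjusted over the list alone, median -0.43, camera adjusted p = 0.18). In NOD, 1 fell and 0 rose (1 and 1 adjusted over the list alone, median -0.081, camera adjusted p = 0.81). With the scaling to one 75th percentile, 1 CD8 T cell marker fell in B10, and in NOD 1 rose and 0 fell. For plasma cells (5 measured), 1 fell and 0 rose in B10 (1 and 0 adjusted over the list alone, median 0.12, camera adjusted p = 0.764, mean -0.073). In NOD, 2 fell and 0 rose (3 and 0 adjusted over the list alone, median -0.60, camera adjusted p = 0.178). For platelets (4 measured), 1 fell and 0 rose in B10 (1 and 0 adjusted over the list alone, median -0.072, camera adjusted p = 0.614). In NOD, 1 fell and 0 rose (1 and 0 adjusted over the list alone, median -0.17, camera adjusted p = 0.203). For erythroid cells (3 measured), 0 rose and 0 fell in B10 (0 and 0 adjusted over the list alone, median 0.29, camera adjusted p = 0.764). In NOD, 0 rose and 0 fell (0 and 0 adjusted over the list alone, median 0.20, camera adjusted p = 0.942). The dendritic cell list passed in NOD with a fixed (adjusted p = 0.0465) or random replicate block (0.0139) and with the scaling to one 75th percentile (0.0256), and the NK cell list in B10 with a fixed (0.0273) or random block (0.0275). With fry the NK cell (0.00011 and 0.000587) and platelet lists (0.0385 and 0.00208) passed in B10 and in NOD. So did CD8 T cells in B10 (0.00368), and plasma cells (0.00191) and dendritic cells (4e-06) in NOD.

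**Figure D2:**
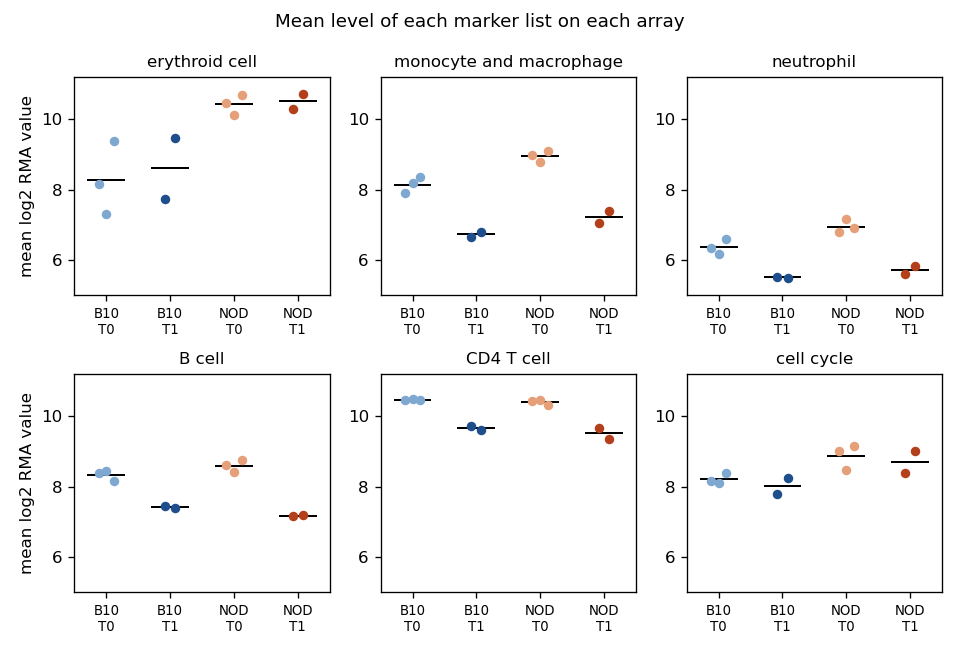
Points are single arrays, showing the mean log2 RMA value of the measured genes of each list, and bars are group means (n = 3 at T0, n = 2 at T1). The erythroid markers reach at most 9.48 on a B10 array and at least 10.1 on a NOD array.

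Before stimulation, most of the genes named as highest in NOD relative to B10 belong to red cells. Car1, carbonic anhydrase of red cells, was 9.63-fold higher in NOD (log2 difference 3.27 ± 0.41, adjusted p = 0.000566). Rhd and Rhag, the Rh blood group proteins, differed by 3.01 ± 0.60 and 2.95 ± 0.78, and Epb42 and Slc4a1, proteins of the red cell membrane, by 2.93 and 2.68. Trim10, Car2 and Aqp1, also active in red cell precursors, differed by 2.66, 2.61 and 2.60, and Tspan8, a tetraspanin, by 2.71. Of 3 measured erythroid markers, 3 were higher and 0 lower in NOD (3 and 0 adjusted over the list alone, median 2.38, camera adjusted p = 0.000157, adjusted p = 0.13 with an estimated correlation). The mean of these markers was 8.16, 7.31 and 9.38 on the B10 T0 arrays and 10.5, 10.1 and 10.7 on those of NOD. The Rhd, Rhag, Epb42, Tspan8, Slc4a1, Trim10, Car2 and Aqp1 calls each ended on omission of NOD_T0 replicate 1 or 3, and those of Rhag and Slc4a1 also without NOD_T0 replicate 2 or NOD_T1 replicate 2 or 3. Without B10_T0 replicate 1 those of Rhag, Epb42, Tspan8, Slc4a1, Trim10, Car2 and Aqp1 ended, and without B10_T0 replicate 2 those of Rhag, Tspan8, Slc4a1, Trim10, Car2 and Aqp1. Over all omissions values were 2.33 to 3.69 for Rhd, 2.09 to 3.80 for Rhag, 2.30 to 3.72 for Epb42 and 2.10 to 3.41 for Tspan8. They were 1.91 to 3.49 for Slc4a1, 2.15 to 3.40 for Trim10, 1.91 to 3.32 for Car2 and 1.97 to 3.25 for Aqp1. With the erythroid marker mean as a covariate, added after the data were seen, none of these red cell and tetraspanin genes passed, and Rhag, Slc4a1, Trim10, Car2 and Aqp1 turned negative. Of these, Car2 is itself part of the covariate. The calls of all named here except Car1 also ended with trend and robust settings and with every probe set tested, and those of Rhag and Slc4a1 with the scaling to one 75th percentile.

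Genes lower in NOD at T0 were of other kinds. Trim12a, of a family of antiviral ubiquitin ligases, was 50.1-fold lower (4.10 ± 0.18 against 9.75 ± 0.18, mean and SD of log2 values, n = 3 each, adjusted p = 3.04e-10). Slc15a2, a peptide transporter, differed by -3.37 ± 0.21 and Abcb1b, a drug efflux pump, by -2.89 ± 0.15. The interferon-inducible genes Ifi213 and Ifi206 differed by -2.38 and -2.38, and Apobec3, which restricts retroviruses, by -2.26. Arhgap31 differed by -2.88, the nucleoside transporter gene Slc28a2b by -2.75, the metabolic kinase Pdk1 by -2.51 and the carboxypeptidase Cpm by -2.18. Ddx43, a helicase, was higher in NOD (2.88 ± 0.19, adjusted p = 3.31e-06). The calls of these 11 genes held when any 1 array was left out and with the erythroid covariate. Probe sets report only the sequences they were designed on, and no sequence of these strains was examined.

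At T0, 1155 genes differed between strains, of which 686 were higher and 469 lower in NOD, and 273 by at least 2-fold. With the erythroid marker mean as a covariate 136 genes were called, 64 higher and 72 lower, while the median standard error of all genes at T0 rose from 0.107 to 0.176. The count was 642 without B10_T0 replicate 1 or 2, 599 without NOD_T0 replicate 1, 571 without NOD_T0 replicate 3 and 2316 with array weights.

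Myeloid markers were higher in unstimulated NOD cells. Of 10 monocyte and macrophage markers, 8 were higher and 0 lower in NOD (9 and 0 adjusted over the list alone, median 0.87, camera adjusted p = 1.33e-12, adjusted p = 0.074 with an estimated correlation). Vcam1, an adhesion molecule, was higher by 1.28 and Cd14, the endotoxin receptor, by 1.27. Of 8 neutrophil markers, 4 were higher and 0 lower in NOD (5 and 0 adjusted over the list alone, median 0.57, camera adjusted p = 3.43e-06, adjusted p = 0.074 with an estimated correlation). Ngp, which encodes a granule protein, was higher by 1.14. Of 9 B cell markers, 1 was higher and 0 lower in NOD (1 and 0 adjusted over the list alone, median 0.24, camera adjusted p = 0.00214, adjusted p = 0.23 with an estimated correlation). Cr2, a complement receptor, was higher by 1.00. Of 7 NK cell markers, 0 were higher and 3 lower in NOD (0 and 3 adjusted over the list alone, median -0.074, camera adjusted p = 0.000619, adjusted p = 0.074 with an estimated correlation). Nkg7, of cytotoxic granules, differed by -1.15. For CD8 T cells (2 measured), 0 were higher and 1 lower in NOD (0 and 1 adjusted over the list alone, median -0.33, camera adjusted p = 0.042, adjusted p = 0.131 with an estimated correlation). For CD4 T cells (7 measured), 0 were higher and 0 lower in NOD (0 and 0 adjusted over the list alone, median -0.056, camera adjusted p = 0.385). Plasma cell markers had 2 higher and 0 lower of 5, 2 and 0 adjusted over the list alone (median 0.091, camera adjusted p = 0.086). Dendritic cell markers had 0 higher and 0 lower of 7, 0 and 0 adjusted over the list alone (median 0.041, camera adjusted p = 0.64). Platelet markers had 0 higher and 0 lower of 4, 0 and 0 adjusted over the list alone (median 0.075, camera adjusted p = 0.28). With the erythroid covariate Vcam1, Cd14, Ngp, Cr2 and Nkg7 no longer passed. The monocyte and macrophage, neutrophil, B cell and NK cell lists passed with it (adjusted p = 8.33e-07, 0.00407, 0.000333 and 0.00407), with medians of 0.491 for monocytes and macrophages and 0.298 for neutrophils. The CD8 list did not pass with it (adjusted p = 0.586), with the scaling to one 75th percentile (0.0523) or with a random replicate block (0.0653), and the B cell list did not with fry (0.0903). The plasma cell list passed with the covariate (0.0151) and with fry (0.0283), and under the scaling 1 of its members was called.

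Cell cycle genes were higher in NOD at T0 as a group. Of 19 measured, 3 were higher and 0 lower in NOD (15 and 0 adjusted over the list alone, median 0.56, camera adjusted p = 6.24e-09, adjusted p = 0.648 with an estimated correlation). Mki67, Ccna2 and Cdk1, all active in dividing cells, differed by 1.85, 1.39 and 1.03. Each of these 3 calls ended without B10_T0 replicate 1, B10_T0 replicate 2, NOD_T0 replicate 1 or NOD_T0 replicate 3, with values over all omissions of 1.53 to 2.23, 1.21 to 1.62 and 0.86 to 1.27, and with the erythroid covariate, under which Mki67 turned negative. They also ended with trend and robust settings and with every probe set tested. The erythroid markers (median 2.38) and the monocyte and macrophage markers (median 0.87) were higher in the same arrays. Of 9 heat shock genes, 1 was higher and 0 lower in NOD (2 and 0 adjusted over the list alone, median 0.092, camera adjusted p = 0.0254, adjusted p = 0.648 with an estimated correlation). Hmox1, heme oxygenase, was higher by 1.23 and also lost its call with the covariate. With it the cell cycle and heat shock lists did not pass either (adjusted p = 0.491 and 0.172).

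Several T cell lists were lower in NOD at T0 by small amounts. For regulatory T cell genes (13 measured), 0 were higher and 4 lower in NOD (0 and 6 adjusted over the list alone, median -0.37, camera adjusted p = 0.000118, adjusted p = 0.648 with an estimated correlation). Capg, an actin regulator, differed by -1.45 and Lrrc32, which holds TGF-beta on the cell surface, by -0.80, while Foxp3, the lineage factor, had a value of -0.024 (adjusted p = 0.971). For T cell receptor signalling (19 measured), 0 were higher and 1 lower in NOD (0 and 3 adjusted over the list alone, median -0.19, camera adjusted p = 0.000967, adjusted p = 0.648 with an estimated correlation). For diabetes candidate genes of NOD mice (19 measured), 1 was higher and 5 lower in NOD (1 and 5 adjusted over the list alone, median -0.18, camera adjusted p = 0.000967, adjusted p = 0.648 with an estimated correlation). Cd226, a costimulatory receptor, differed by -0.87 and Ptpn22, a phosphatase of T cell receptor signalling, by -0.60. For negative feedback regulators (25 measured), 0 were higher and 4 lower in NOD (2 and 6 adjusted over the list alone, median -0.20, camera adjusted p = 0.00867, adjusted p = 0.648 with an estimated correlation). Nfkbid, an NF-kB regulator, differed by -0.69. For T helper lineage regulators (16 measured), 0 were higher and 2 lower in NOD (0 and 2 adjusted over the list alone, median -0.15, camera adjusted p = 0.0254, adjusted p = 0.648 with an estimated correlation). With the erythroid covariate the direction of the T helper list reversed (adjusted p = 0.491). The other 4 lists did not pass with it, at 0.982 for regulatory T cells, 0.199 for receptor signalling, 0.772 for diabetes candidates and 0.982 for negative feedback. With the covariate, Capg, Lrrc32, Cd226, Ptpn22 and Nfkbid no longer passed. The erythroid, myeloid and B cell markers were higher in the same arrays.

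Glycolysis and nutrient transport genes were lower in NOD at T0 by the list test (0 higher and 0 lower of 17, 0 and 0 adjusted over the list alone, median -0.12, camera adjusted p = 0.0326, adjusted p = 0.704 with an estimated correlation). Interferon-stimulated genes were lower too (2 higher and 1 lower of 20, 2 and 8 adjusted over the list alone, median -0.29, camera adjusted p = 0.00489, adjusted p = 0.648 with an estimated correlation). Rtp4, an interferon-inducible chaperone, was lower (-0.99), while Isg20, an RNase, and Rsad2 were higher (1.15 and 1.71), against the direction of the list. Their calls ended without NOD_T0 replicate 1 and, for Isg20 and Rsad2, without B10_T0 replicate 1 or NOD_T0 replicate 3. The Rtp4 and Rsad2 calls also ended without B10_T0 replicate 2, and that of Rtp4 without NOD_T0 replicate 2. Values over omissions were -1.22 to -0.67, 0.94 to 1.32 and 1.44 to 2.16, and with the erythroid covariate all 3 calls ended and Rsad2 turned negative. The 3 calls also ended with trend and robust settings and with every probe set tested, and that of Rtp4 without both B10 arrays of replicate 3. With the covariate neither list passed (adjusted p = 0.347 for glycolysis and 0.337 for interferon-stimulated genes), nor did glycolysis with a fixed or random replicate block (0.0524 and 0.106). With fry none of the 9 gene lists that passed at T0 did so (adjusted p from 0.12 to 0.352).

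The remaining lists at T0 did not pass the list test without a covariate. Effector cytokines had 1 higher and 2 lower of 18, 1 and 2 adjusted over the list alone (median -0.035, camera adjusted p = 0.351). The higher member was Il2, while Il4 differed by -1.01 and Tnf by -0.54. Chemokines and receptors had 1 higher and 2 lower of 16, 2 and 3 adjusted over the list alone (median -0.046, camera adjusted p = 0.483). Ccl5, an attractant of T cells, differed by -1.44. MHC and antigen presentation genes had 0 higher and 4 lower of 14, 2 and 4 adjusted over the list alone (median -0.00088, camera adjusted p = 0.483). Psmb8, an immunoproteasome subunit, differed by -0.62. Activation surface molecules had 2 higher and 4 lower of 17, 2 and 4 adjusted over the list alone (median -0.18, camera adjusted p = 0.136). With the erythroid covariate this list turned to the opposite direction and passed (adjusted p = 0.0301), with 0 members called either way. Immediate response transcription factors had 1 higher and 2 lower of 24, 1 and 2 adjusted over the list alone (median -0.13, camera adjusted p = 0.202). Naive genes had 0 higher and 0 lower of 18, 0 and 0 adjusted over the list alone (median 0.076, camera adjusted p = 0.159). Ribosome biogenesis had 1 higher and 2 lower of 20, 1 and 2 adjusted over the list alone (median -0.051, camera adjusted p = 0.982). Amino acid starvation genes had 1 higher and 1 lower of 13, 2 and 1 adjusted over the list alone (median 0.068, camera adjusted p = 0.102). Cholesterol synthesis had 2 higher and 1 lower of 14, 3 and 1 adjusted over the list alone (median 0.12, camera adjusted p = 0.136). Apoptosis regulators had 2 higher and 1 lower of 15, 2 and 1 adjusted over the list alone (median 0.020, camera adjusted p = 0.483). With the covariate Il4, Tnf, Ccl5 and Psmb8 no longer passed. Under the scaling to one 75th percentile, chemokines and receptors had 0 higher and 2 lower, and immediate response factors 1 and 1.

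After stimulation, type 2 cytokine genes were among the largest differences. Il4, which drives type 2 helper responses, was 7.41-fold lower in NOD (log2 difference -2.89 ± 0.23, adjusted p = 3.42e-05, 9.19 ± 0.24 against 12.08 ± 0.50, mean and SD, n = 2 each). Il5, the eosinophil cytokine, was 4.35-fold lower (-2.12 ± 0.37, adjusted p = 0.0092) and Il13, which acts on epithelia, differed by -1.76 ± 0.22. Arg1, an arginine-degrading enzyme, was 5.12-fold lower (-2.36 ± 0.16). Of 18 effector cytokines, 0 were higher and 6 lower in NOD (1 and 9 adjusted over the list alone, median -0.37, camera adjusted p = 3.39e-07, adjusted p = 0.516 with an estimated correlation). Csf2 differed by -1.52, Il17a by -1.08 and Il3 by -0.93. The Il5 call ended without NOD_T1 replicate 3, with values over omissions of -3.01 to -1.23. The Il17a call ended without B10_T1 replicate 3 or NOD_T1 replicate 2 (-1.27 to -0.88), and the Il3 call without B10_T1 replicate 2 or NOD_T1 replicate 3 (-1.30 to -0.57). With the erythroid covariate, or with only the arrays of these groups, Il5 and Il3 no longer passed. The Il5 call also ended with trend and robust settings, the Il3 call with every probe set tested, and the Il17a call with array weights or without both B10 arrays of replicate 3. T cell markers in these arrays had a median of -0.25, and erythroid markers one of 2.04.

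**Figure D3:**
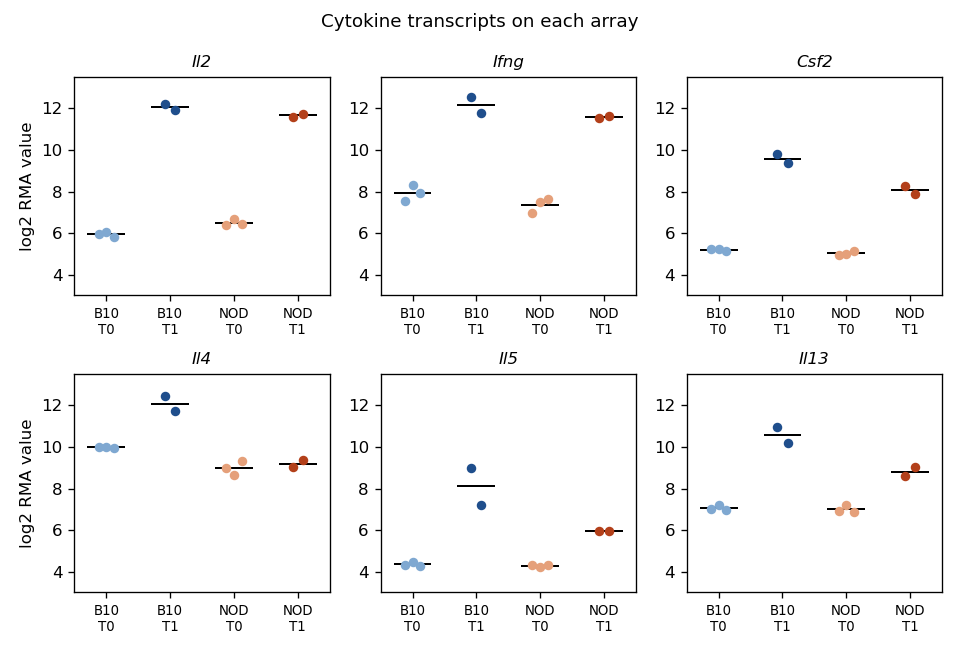
Points are single arrays, showing the log2 RMA value of 6 cytokine transcripts, and bars are group means (n = 3 at T0, n = 2 at T1). Il4 lies at 12.4 and 11.7 on the stimulated B10 arrays and at 9.02 and 9.36 on those of NOD.

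Of 16 chemokine and receptor genes at T1, 0 were higher and 4 lower in NOD (0 and 5 adjusted over the list alone, median -0.32, camera adjusted p = 8.58e-05, adjusted p = 0.571 with an estimated correlation). With every array shifted to one 75th percentile 2 were lower. With the erythroid covariate the list did not pass (adjusted p = 0.183), nor with fry (0.227). Ccl5 differed by -1.52 and Xcl1 by -1.18, and neither passed with the erythroid covariate. Cd160, a receptor of cytotoxic lymphocytes, was lower in NOD (-2.05 ± 0.21). Trim12a (-3.93), Slc15a2 (-2.45), Abcb1b (-2.41) and Slc28a2b (-2.22) were lower in NOD after stimulation as before it. The interferon-inducible genes Ifi214 and Ifi209 differed by -2.40 and -2.06. Higher in NOD were Nts, which encodes the peptide neurotensin (2.57 ± 0.17), Dhrs3, a retinaldehyde reductase (2.27 ± 0.15), Ccnb1ip1 (2.14), Cln8 (2.11) and Zfp979 (2.09). The erythroid markers had a median of 2.04 in the same arrays and the monocyte and macrophage markers one of 0.52.

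Red cell genes and interferon-stimulated genes were also higher in stimulated NOD cells. Rhd differed by 3.25 ± 0.74, Car1 by 2.30, Gda, a guanine deaminase, by 2.38 and Fech, the enzyme that completes heme, by 2.25. Of 20 interferon-stimulated genes, 5 were higher and 0 lower in NOD (8 and 0 adjusted over the list alone, median 0.45, camera adjusted p = 1.45e-05, adjusted p = 0.571 with an estimated correlation), among them the antiviral gene Rsad2 (2.20) and Stat2, a transcription factor of the interferon response (0.89). Without B10_T1 replicate 2 or NOD_T1 replicate 3 the calls of Rhd, Gda, Car1, Fech, Rsad2 and Stat2 all ended. Those of Rhd, Gda, Fech and Rsad2 ended without NOD_T0 replicate 1 or NOD_T1 replicate 2, and those of Rhd and Fech also without B10_T0 replicate 1. Values over all omissions were 2.24 to 4.25 for Rhd, 1.32 to 3.45 for Gda, 1.67 to 2.93 for Car1, 1.35 to 3.16 for Fech, 1.34 to 3.06 for Rsad2 and 0.68 to 1.11 for Stat2. These 6 genes did not pass with the erythroid covariate, with array weights or with only the arrays of these groups. The calls of Rhd, Gda, Car1, Fech and Rsad2 also ended with every probe set tested and with trend and robust settings, and that of Stat2 without both B10 arrays of replicate 3. With fry the interferon list did not pass (adjusted p = 0.286). Of 3 erythroid markers, 0 were higher and 0 lower in NOD (3 and 0 adjusted over the list alone, median 2.04, camera adjusted p = 0.00535, adjusted p = 0.387 with an estimated correlation). The direction of the erythroid list reversed with the covariate it forms (adjusted p = 0.862), and with fry the list did not pass (0.124).

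At T1, 718 genes differed between strains (353 higher and 365 lower in NOD), 207 of them by at least 2-fold (135 higher, 72 lower). This balance depends on the processing. Higher and lower genes numbered 397 and 269 with every array shifted to one 75th percentile, 561 and 362 with a replicate block, 356 and 501 with trend and robust settings, and 247 and 375 with every probe set tested. With the erythroid covariate 128 were called, without B10_T1 replicate 2 184, without NOD_T1 replicate 3 270, with array weights 292 and with only the arrays of these groups 128. Between both states, 200 genes were higher in NOD at T0 and at T1, against 12.1 if calls were independent, and 156 were lower at both, against 8.59. Calls were opposite for 5 genes, and across genes Pearson's r was 0.619 and the Spearman correlation 0.289. Both states used the same spread estimate per gene, and arrays of equal replicate number may share a source, so calls were not fully independent. With the erythroid covariate 19 genes were higher and 30 lower in NOD at both times.

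Among the other lists at T1, cell cycle genes had 0 higher and 0 lower of 19, 13 and 0 adjusted over the list alone (median 0.76, camera adjusted p = 4.93e-06, adjusted p = 0.571 with an estimated correlation). Monocyte and macrophage markers had 1 higher and 0 lower of 10, 7 and 0 adjusted over the list alone (median 0.52, camera adjusted p = 0.000233, adjusted p = 0.387 with an estimated correlation). Vcam1 was higher by 1.09. Lower in NOD by the list test were diabetes candidate genes (0 higher and 2 lower of 19, 0 and 2 adjusted over the list alone, median -0.23, camera adjusted p = 0.00536, adjusted p = 0.571 with an estimated correlation). So were regulatory T cell genes (1 higher and 2 lower of 13, 1 and 4 adjusted over the list alone, median -0.34, camera adjusted p = 0.0142, adjusted p = 0.571 with an estimated correlation). MHC and antigen presentation genes were lower by this test (0 higher and 1 lower of 14, 1 and 4 adjusted over the list alone, median -0.15, camera adjusted p = 0.0143, adjusted p = 0.571 with an estimated correlation). T helper lineage regulators had a lower list value (0 higher and 0 lower of 16, 0 and 2 adjusted over the list alone, median -0.14, camera adjusted p = 0.0194, adjusted p = 0.571 with an estimated correlation). Immediate response transcription factors passed the list test as well (0 higher and 0 lower of 24, 0 and 0 adjusted over the list alone, median -0.16, camera adjusted p = 0.0219, adjusted p = 0.571 with an estimated correlation). Icos, an Idd candidate and costimulatory receptor, differed by -0.93, a call that ended without B10_T1 replicate 2 (values over omissions -1.10 to -0.76). Amino acid starvation genes had 1 higher and 1 lower of 13, 6 and 1 adjusted over the list alone (median 0.30, camera adjusted p = 0.0112, adjusted p = 0.571 with an estimated correlation). Vcam1 and Icos did not pass with the erythroid covariate or with only the arrays of these groups. With the covariate the directions of the T helper (adjusted p = 0.934) and regulatory T cell lists (0.608) reversed. Also with it, cell cycle (0.223), diabetes candidates (0.608), MHC (0.562), immediate response factors (0.231), amino acid starvation (0.165) and monocytes and macrophages (0.185) did not pass. With fry, too, none of these lists passed (adjusted p from 0.124 to 0.322). Under the scaling to one 75th percentile, higher and lower members numbered 3 and 0 for amino acid starvation, 1 and 1 for regulatory T cells, 0 and 1 for diabetes candidates, 0 and 0 for MHC, and 2 and 0 for monocytes and macrophages. The erythroid markers had a median of 2.04 in these arrays.

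No other list passed the test at T1. Glycolysis genes had 0 higher and 1 lower of 17, 0 and 1 adjusted over the list alone (median -0.008, camera adjusted p = 0.309). Pfkp, a glycolytic enzyme, differed by -1.04, a call that ended with the covariate. Heat shock genes had 1 higher and 1 lower of 9, 1 and 2 adjusted over the list alone (median -0.12, camera adjusted p = 0.0578). T cell receptor signalling genes had 1 higher and 0 lower of 19, 1 and 0 adjusted over the list alone (median -0.19, camera adjusted p = 0.0578). Activation surface molecules had 1 higher and 3 lower of 17, 1 and 4 adjusted over the list alone (median -0.12, camera adjusted p = 0.104). Negative feedback regulators had 0 higher and 1 lower of 25, 0 and 1 adjusted over the list alone (median -0.11, camera adjusted p = 0.129), and 0 and 0 under the scaling to one 75th percentile. Naive genes had 1 higher and 0 lower of 18, 1 and 0 adjusted over the list alone (median -0.037, camera adjusted p = 0.957, mean 0.012). Ribosome biogenesis had 1 higher and 0 lower of 20, 1 and 0 adjusted over the list alone (median -0.054, camera adjusted p = 0.236). Cholesterol synthesis had 0 higher and 0 lower of 14, 0 and 0 adjusted over the list alone (median -0.039, camera adjusted p = 0.833). Apoptosis regulators had 0 higher and 0 lower of 15, 0 and 0 adjusted over the list alone (median 0.098, camera adjusted p = 0.767). B cell markers had 0 higher and 1 lower of 9, 0 and 2 adjusted over the list alone (median -0.15, camera adjusted p = 0.0627). NK cell markers had 0 higher and 0 lower of 7, 0 and 2 adjusted over the list alone (median -0.19, camera adjusted p = 0.0627). Neutrophil markers had 0 higher and 0 lower of 8, 0 and 0 adjusted over the list alone (median 0.17, camera adjusted p = 0.225). CD4 T cell markers had 0 higher and 0 lower of 7, 1 and 2 adjusted over the list alone (median -0.25, camera adjusted p = 0.204). CD8 T cell markers had 0 higher and 0 lower of 2, 0 and 0 adjusted over the list alone (median 0.017, camera adjusted p = 0.986). Plasma cell markers had 0 higher and 0 lower of 5, 0 and 0 adjusted over the list alone (median -0.11, camera adjusted p = 0.653, mean 0.0012). Dendritic cell markers had 0 higher and 0 lower of 7, 0 and 0 adjusted over the list alone (median 0.048, camera adjusted p = 0.467). Platelet markers had 0 higher and 0 lower of 4, 0 and 0 adjusted over the list alone (median 0.013, camera adjusted p = 0.859, mean -0.031).

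The interaction asks which responses themselves differed, and it called 49 genes, 19 with a higher NOD response and 30 with a lower one. These numbers were 16 and 15 with every array shifted to one 75th percentile and 25 and 14 with every probe set tested, so the balance depends on the processing. Il4, Il13 and Csf2 responded less in NOD, with log2 interaction values of -1.88 ± 0.29 (adjusted p = 0.0216), -1.70 ± 0.28 (adjusted p = 0.0307) and -1.34 ± 0.20 (adjusted p = 0.0175). Il5 had a value of -2.05 ± 0.48 (adjusted p = 0.137) and did not pass. Ifi202b, an interferon-inducible gene, rose by 4.62 in B10 and 2.34 in NOD, an interaction of -2.28 ± 0.15 (adjusted p = 3.36e-05), and Arg1 had one of -2.12 ± 0.21. Nts rose in NOD from 3.67 to 6.33, an interaction of 2.41 ± 0.22. Arhgap31 had an interaction of 2.41 ± 0.22, from 6.44 at T0 in NOD and 9.32 in B10. The Il4 call ended without B10_T0 replicate 1, 2 or 3, B10_T1 replicate 2, NOD_T0 replicate 1, or NOD_T1 replicate 2 or 3 (values over omissions -2.24 to -1.52). The Il13 call ended without each of these arrays except B10_T0 replicate 2, and also without NOD_T0 replicate 2 or 3 (-2.07 to -1.32). The Csf2 call ended without B10_T0 replicate 1 or 3, B10_T1 replicate 2, NOD_T0 replicate 3 or NOD_T1 replicate 3 (-1.55 to -1.13). With every probe set tested the calls of Il4, Il13 and Csf2 ended. The Il4 call also ended with trend and robust settings, and the Il13 call with array weights or the scaling to one 75th percentile. The calls of Ifi202b, Arg1, Nts and Arhgap31 held under every omission of 1 array.

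Effector cytokines responded less in NOD as a list (0 positive and 3 negative of 18, 0 and 7 adjusted over the list alone, median -0.39, camera adjusted p = 4.15e-06, adjusted p = 0.361 with an estimated correlation). Chemokines and receptors had lower interaction values (0 positive and 0 negative of 16, 0 and 5 adjusted over the list alone, median -0.23, camera adjusted p = 0.00129, adjusted p = 0.695 with an estimated correlation). Their median response was 1.14 in B10 and 1.56 in NOD. Interferon-stimulated genes had higher interaction values (1 positive and 0 negative of 20, 6 and 0 adjusted over the list alone, median 0.59, camera adjusted p = 1.08e-10, adjusted p = 0.361 with an estimated correlation). The called member, Oas3, an antiviral enzyme, had 0.97, a call that ended on omission of any array except B10_T0 replicate 1 (values over omissions 0.85 to 1.08). It also ended with every probe set tested, with array weights and without both B10 arrays of replicate 3. The median response of the list was 0.22 in NOD and -0.53 in B10. Heat shock genes (0 positive and 0 negative of 9, 0 and 2 adjusted over the list alone, median -0.32, camera adjusted p = 9.21e-05, adjusted p = 0.361 with an estimated correlation) responded less. B cell markers had lower interaction values by the list test (0 positive and 2 negative of 9, 0 and 4 adjusted over the list alone, median -0.24, camera adjusted p = 0.000124, adjusted p = 0.25 with an estimated correlation). The 2 members were Cd79a (-1.25) and Cr2 (-1.44), and Cr2 went from 7.45 to 8.82 in B10 and from 8.45 to 8.38 in NOD. The Cr2 call ended on omission of any array except NOD_T0 replicate 2 (values over omissions -1.60 to -1.26), and the Cd79a call on omission of any except B10_T0 replicate 2, B10_T1 replicate 3 and NOD_T1 replicate 2 (-1.42 to -1.07). Both calls also ended with every probe set tested, and that of Cr2 with array weights or without both B10 arrays of replicate 3. Markers of monocytes and macrophages also had lower interaction values (0 positive and 0 negative of 10, 0 and 0 adjusted over the list alone, median -0.25, camera adjusted p = 0.00535, adjusted p = 0.36 with an estimated correlation), as did those of neutrophils (0 positive and 0 negative of 8, 0 and 1 adjusted over the list alone, median -0.40, camera adjusted p = 0.00535, adjusted p = 0.25 with an estimated correlation). With the scaling to one 75th percentile, no B cell marker or interferon-stimulated gene and 2 effector cytokines were called. With the erythroid covariate 6 effector cytokines were. With fry none of these 7 lists passed (adjusted p from 0.119 to 0.705). The remaining lists did not pass, with camera adjusted p from 0.0591 to 0.871. With a replicate block plasma cells (adjusted p = 0.0055), NK cells (0.0334, and 0.0196 with a random block) and amino acid starvation (0.0428) passed, and plasma cells also with the erythroid covariate (0.0232).

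The interaction count was 13 without B10_T1 replicate 2, 19 without NOD_T1 replicate 3, 21 and 22 without replicate 1 of NOD_T0 and of B10_T0, 25 and 28 without replicate 3 of each, and 32 and 29 without replicate 2 of each. It was 80 with the erythroid covariate, 90 with a replicate block, 102 with trend and robust settings, and 31 with array weights or the scaling to one 75th percentile. Lists passed the test in 47 cases over the 5 contrasts and marker lists in 20, and with an estimated correlation 0 and 0 passed.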

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

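The test of T cell markers below was chosen only after the cytokine values were seen, and the test of memory genes was written before its result.

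In 20 named genes the change of the signal on stimulation differed between strains, by limma's test of the interaction (NOD response minus B10 response, log2). The values were Nts 2.41, Arhgap31 2.41, Trim12a 1.72, Dhrs3 1.69, Dipk1a 1.46, Pttg1 1.40, Pmp22 1.36, Klrb1c 1.08, Lgals9 1.07 and Irak1bp1 1.03 for larger values in NOD. They were Ifi202b -2.28, Arg1 -2.12, Il4 -1.88, Il13 -1.70, Klra17 -1.64, Cr2 -1.44, Crtam -1.37, Csf2 -1.34, Lgals3 -1.33 and Ubash3b -1.33 for smaller ones. Leaving out 1 array ended the call of 12 of these 20 genes in at least 1 case. Trim12a went from 9.75 to 7.75 in B10 and from 4.10 to 3.82 in NOD, Klrb1c from 5.72 to 4.29 and from 4.49 to 4.14, and Klra17 from 5.00 to 4.46 and from 6.60 to 4.43. In each of these 3 genes 1 strain started lower and may have had little room to fall. Background levels are not used here, so this was not tested. Their interaction does not by itself show a different response.

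For lists, the medians of the interaction were -0.39 for effector cytokines, -0.23 for chemokines and chemokine receptors, 0.59 for interferon-stimulated genes and -0.32 for heat shock genes. Among markers they were -0.24 for B cells, -0.25 for monocytes and macrophages and -0.40 for neutrophils. The camera adjusted p were 4.15e-06, 0.00129, 1.08e-10, 9.21e-05, 0.000124, 0.00535 and 0.00535. With an estimated correlation they were 0.361, 0.695, 0.361, 0.361, 0.25, 0.36 and 0.25, so that none passed.

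Il4, Il5 and Il13 were lower in stimulated NOD cells, with a median log2 difference of -2.12. A smaller share of T cells would lower T cell markers by about as much, but the 7 markers had a median of -0.247 (median standard error 0.134), which argues against a smaller share as the whole cause. Fewer memory T cells in NOD at T0 might also lower these cytokines. The 16 memory genes had a median of -0.201 then (camera p = 0.0548, and p = 0.52 with an estimated correlation). Of these, 1 (Rora) was lower by its own test, though not with the erythroid covariate, and 0 higher. T cell receptor signalling genes had -0.19 and naive genes 0.076, so this stays open. Other technical explanations, such as sequence variants under the probes of these 3 genes, were not tested. A strain difference in the response itself also stays open, as a hypothesis.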

How the results depend on the processing

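Chosen only after the data were seen were the tests with the erythroid covariate and without both B10 arrays of replicate 3. Of the 5 counts, both stimulation counts stayed within 1.5 times under every alternative except the 2-fold minimum. Genes called in B10, in NOD, between strains at T0, at T1 and in the interaction numbered 6342, 7085, 1155, 718 and 49. With at least a 2-fold change the first 4 were 1876, 1812, 273 and 207, fewer by construction. The T0 count was 2316 with array weights and 136 with the erythroid covariate. The T1 count was 292 with array weights, 128 with the covariate and 128 with only the 2 groups compared. The interaction count was 31 with array weights, 31 with one 75th percentile, 102 with trend and robust settings, 90 with a replicate block and 80 with the covariate. For these moved counts the cause was not tested, except that the covariate raised the median standard error from 0.107 to 0.176 at T0. List calls were 31 with fry (47 with camera), and 0 and 0 for gene and marker lists with an estimated correlation.

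Leaving out 1 array, counts ranged over 5376 to 6596 in B10, 5915 to 7071 in NOD, 571 to 1306 at T0, 184 to 889 at T1 and 13 to 69 in the interaction. The list tests were not run with arrays left out. A group left with 1 array was assumed to vary like the others. Counts moved by over 1.5 times at T0 without B10_T0 replicate 1 (642) or 2 (642) and NOD_T0 replicate 1 (599) or 3 (571), and at T1 without B10_T1 replicate 2 (184) or NOD_T1 replicate 3 (270). In the interaction they moved without B10_T0 replicate 1 (22), 2 (29) or 3 (28), B10_T1 replicate 2 (13), NOD_T0 replicate 1 (21), 2 (32) or 3 (25) and NOD_T1 replicate 3 (19). Without both B10 arrays of replicate 3 the counts were 4876, 6992, 1048, 753 and 48.

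Reversed at T0 with the covariate were Rhag -0.63, Slc4a1 -0.57, Trim10 -0.076, Aqp1 -0.13, Rsad2 -0.056 and Mki67 -0.19, and Car2 -0.24 and Klf1 -0.032, which are part of it. List directions reversed with the covariate are given as adjusted p. At T0 they were 0.199 for effector cytokines, 0.0301 for activation surface molecules, 0.337 for naive genes, 0.199 for chemokines, 0.491 for T helper regulators, 0.601 for MHC, 0.728 for CD4 T cells and 0.864 for erythroid cells. At T1 they were 0.183 for activation surface molecules, 0.665 for negative feedback, 0.881 for cholesterol synthesis, 0.608 for regulatory T cells, 0.934 for T helper regulators, 0.798 for plasma cells and 0.862 for erythroid cells. They were 0.559 for cell cycle and 0.792 for diabetes candidates in the interaction, and 0.903 in B10 and 0.875 in NOD for erythroid cells on stimulation. Of these, T helper regulators (T0 and T1), regulatory T cells at T1 and erythroid cells (T0 and T1) had passed, and the erythroid list forms the covariate, while activation surface molecules at T0 passed only with it.

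Other settings reversed the direction of lists that had not passed. With fry these were T helper regulators in B10 (0.221) and NOD (0.291), naive genes at T1 (0.96) and activation surface molecules in the interaction (0.995). With a replicate block they were cell cycle (0.0629), apoptosis (0.629) and diabetes candidates (0.974) in the interaction. With a random block they were T helper regulators in B10 (0.484) and NOD (0.63), ribosome biogenesis at T0 (0.95), naive genes (0.886) and CD8 T cells (0.997) at T1. With one 75th percentile the erythroid list in NOD (0.853) reversed. Except for the covariate's own markers, the cause was not tested. Named genes and list members lost a call in 101 cases with the covariate and in 91 with every probe set tested. Background intensity is not used here, so what it limits is unknown.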

Other observations

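Chosen only after the results were seen were the test of cell cycle genes with the erythroid covariate, and for neighbouring genes the margin that decides the comparison and the counts of stimulation genes set against the 4 and the 154 pairs.

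Some genes differing between strains at T0 are genome neighbours, singled out after their values were seen. The interferon-inducible genes Ifi206, Ifi208, Ifi209, Ifi213 and Ifi214 lie together and had log2 differences (NOD minus B10) of -2.38, -1.51, -1.46, -2.38 and -1.56. The lymphocyte GTPase genes Gimap1, Gimap3, Gimap4, Gimap5 and Gimap7 had -0.38, -0.62, -0.33, -0.55 and -1.003. Next to the drug efflux pumps Abcb1a (-0.69) and Abcb1b (-2.89), Abcb4 (1.39), Crot (-0.45), Rundc3b (-1.42) and Slc25a40 (-0.58) also differed. The NK receptor genes Klrd1, Klrk1, Klrc1 and Klrc2 had -0.94, -0.46, -0.87 and -1.31. The lectin genes Clec4a2, Clec4n, Clec4d and Clec4e, active in myeloid cells, had 0.57, 1.30, 0.86 and 0.72.

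Split by strain, the 6 unstimulated arrays fitted alone gave 1420 called genes, and other splits at most 0. Only 1 of the 10 splits gave as many, and 10 are too few for a share under 0.05.

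Cell cycle genes were higher in NOD at T0 with a median of 0.558 (median standard error of members 0.201), and erythroid markers were higher in the same arrays although beads were used to select CD4-positive cells. Red cell precursors divide, so a larger share of them in the NOD samples is a candidate explanation: with the erythroid marker mean as a covariate the median was 0.0639 (median standard error 0.277). The covariate and the strain nearly coincide, so both the smaller value and the larger error ended the calls. Within B10, where strain plays no part, 14 of 19 cell cycle genes had a slope above 0 on the erythroid marker mean, against 48.7% of all genes, over 5 arrays, which just meets the 14 set beforehand. Replicate 3 had the highest marker mean in both states (9.38 against 8.16 and 7.31 at T0, 9.48 against 7.74 at T1). These slopes thus rest mostly on replicate 3 against replicate 2, and the 19 genes are not independent replicates. Car2 and Slc4a1 reached 11.74 and 11.51 in NOD (log2), the globin genes have no probe set with a single symbol, and these values are consistent with erythroid cells, but a higher division rate of T cells in NOD was not tested apart from them.

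Sequence variants that weaken probe binding in NOD could lower the signal of a gene. For genes lower at both times, 30 with the erythroid covariate and 156 without it, this explanation stays open: 200 genes were higher at both times without the covariate, the opposite balance, and 19 with it. With the covariate, 61.2% of the genes called the same way at both times were lower (exact 95% interval 46.2% to 74.8%, exact two-sided binomial p = 0.152). Blocks of genome that differ between the strains may hold several differing genes: called neighbours with different name stems were 1.92 times as many as chance would give (110 pairs against 57.4, p = 1e-04, the smallest that 10000 permutations can give). Equally many genes responding to stimulation in B10 gave 98 pairs, and the difference of 12 lies within 28.8, which is 2 times its counting spread. Of the genes called with the erythroid covariate 4 pairs were neighbours, against 0.788 by chance (permutation p = 0.007), and equally many stimulation genes gave 3. With pairs of 1 name stem included the counts were 154 and 115, a difference of 39, above 32.8 (2 times its spread). These pairs hold gene families, so blocks cannot be told apart from neighbouring genes changing together.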
